A study of Homo sapiens with 6 samples.

How the data were processed

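Stranded mRNA libraries had been prepared from 6 samples of human iPS cell-derived neural cells expressing hM3Dq, 3 treated with 5 uM CNO and 3 with vehicle for 2 h, and sequenced as 150-bp pairs, per the labels' protocols. The labels give each sample a differently numbered iPS line. Whether these numbers stand for separate lines could not be settled from the sources used here, and line was not used as a factor, since it is not separable from sample. Apart from these numbers nothing in the labels says that the replicates came from separate cultures. Unless they did, p-values measure only the spread between these samples, which may be technical.

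The submitters' processing notes name Trim Galore 0.6.6, a read trimmer, and Salmon 1.4.0, which estimates transcript abundance from reads. The authors deposited per sample an estimated count, a TPM value, a length and an effective length for 71157 rows, of which 38701 carry a gene symbol and 32456 a transcript identifier, per the file headers and contents. The genome build and annotation were not given in the sources used here. Estimated counts share reads among similar sequences by a model, so copies of a gene can exchange counts between libraries. TPM are scaled to the same total in each library and hold no depth. The length and effective length, in bases, are the authors' deposited values and served 2 checks only.

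Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, and the quasi-likelihood test of CNO against vehicle over all 6 samples with no covariate. This left 18646 rows. Calls are at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 change was taken as its size divided by the square root of F. The SE of a list's median came from the spread over its genes. It treats genes as independent and holds no spread between libraries. The common biological coefficient of variation was 3.79%. No pair of libraries of the same group agreed within sampling noise over rows with at least 20 counts, so all 6 were counted. Total estimated counts ran from 20010285 to 30157141, and the floor of 3 counts covers counting error only.

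A family of 41 gene lists (pathways, quality markers and cell type markers) was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 41. The samples' groups, the test, the lists and the rule for named genes were fixed before the data were examined. The rule names CHRM3, FOS, FOSB, EGR1, NPAS4, ARC, NR4A1 and BDNF; the 10 largest rises and 10 largest falls among called rows with a symbol, a mean of at least 1 CPM and no overlap between groups; the 5 smallest p-values per direction; and up to 4 members per list with the smallest p-values. Lists with no called member are summarised in place of their examples, and some genes are not reported here. EGR4, FOSL1, FOSL2, TAGLN, GEM, PDE4D, DDIT3, VIM, the relatives of pseudogenes and readthrough rows, and the further genes of the closing observations were named after their values were seen.

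Alternatives replaced the scaling (RLE factors, library size), the filter (none, or 10 CPM in 3 samples), the tool (DESeq2 1.42.0, limma-voom) or the unit (limma on log2(TPM + 1) and log2(TPM + 0.1) for rows with a mean TPM of at least 1), added the replicate number as a block, or left out each library. For lists, an estimated correlation, fry and ranks were tried. Alternatives chosen after seeing the data used symbol rows only, CNO replicate 1 alone, the mean of the mesenchymal and fibroblast list as a covariate, loess corrections (span 0.3) for GC content and length of GENCODE release 29 transcripts, effective lengths as offsets, and the newer edgeR quasi-likelihood fit. GC content and length were known for 94.2% of tested rows.

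The test was tried on simulated data with the real means and library sizes, in 5 draws with 200 changed genes each. With trended dispersions 35 of 769 calls (4.55%) were false. With dispersions estimated per row 83 of 783 (10.6%) were false, above the nominal share, so that adjusted p-values just under 0.05 may be too small.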

Results

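Messenger RNA was measured by sequencing in human neural cells that had been differentiated from iPS cell-derived neural stem and progenitor cells and that expressed hM3Dq. This receptor is an engineered form of the M3 muscarinic acetylcholine receptor, couples to Gq proteins and responds to the drug clozapine-N-oxide (CNO). Cells in 3 samples had received 5 uM CNO and cells in 3 control samples the vehicle, each for 2 h. The design asks which mRNAs differ after 2 h of receptor stimulation. The estimated counts per library came to 28200131, 20010285 and 28849779 for CNO replicates 1, 2 and 3. They came to 25333011, 20501268 and 30157141 for vehicle replicates 1, 2 and 3. A floor of 3 counts in 1 library corresponds to between 0.0992 and 0.15 CPM. Unless stated otherwise, values are mean ± SD in CPM (counts scaled to a common library total) over the 3 libraries of a group. Changes are log2 fold changes of CNO over vehicle ± SE, and adjusted p-values of single genes are from edgeR's quasi-likelihood test.

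Exposure to CNO was followed by a response made up mostly of rises. The 4 largest rises that the naming rule selects were those of the transcription factor genes FOSB, EGR3, EGR2 and EGR1. FOSB, a subunit of AP-1, rose from 0.581 ± 0.227 CPM to 20.2 ± 1.99 CPM, a log2 change of 5.17 ± 0.17 (edgeR adjusted p = 3.21e-09). EGR3 rose by 4.02 ± 0.17 (adjusted p = 3.55e-08), EGR2 by 3.68 ± 0.19 (2.15e-07) and EGR1 by 3.11 ± 0.083 (8.64e-10). The size of these rises depended on the alternative. Changes ran from 3.01 to 5.48 for FOSB, 2.64 to 4.24 for EGR3, 1.75 to 3.77 for EGR2 and 2.79 to 3.2 for EGR1. Vehicle means lay below 1 TPM for FOSB, EGR3 and EGR2 (0.632, 0.478 and 0.336). Adding 1 TPM before taking the log therefore shrinks their changes by arithmetic alone. In the deposited TPM values FOSB went from 0.632 ± 0.69 with vehicle to 11.5 ± 0.46 with CNO. Over the whole transcriptome, edgeR called 431 of 18646 tested rows higher and 67 lower at an adjusted p under 0.05. Of these, 72 were higher and 6 lower by at least 2-fold. The 6 include the pseudogene rows SLC2A3P1 and RAB43P1, which have near-identical copies and are uncertain. The median change was 0.37 among the higher calls and -0.22 among the lower calls, and the median of all tested rows was -0.0038. At an unadjusted p under 0.05 there were 2841 rows. The 2 groups did not overlap in CPM in 19.7% of tested rows, where chance gives 10%. The number of lower calls depended on single libraries: it was 40 without CNO replicate 1, 27 without CNO replicate 2, 133 without vehicle replicate 1, 29 without vehicle replicate 2 and 32 without vehicle replicate 3. The number of higher calls was 284 without vehicle replicate 3. With no low-count filter the counts were 934 higher and 553 lower, and on log2(TPM + 1) limma called 181 higher and 13 lower.

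The transcript of CHRM3, the gene from which hM3Dq was engineered, was abundant in all 6 libraries. It stood at 1312 ± 26.8 CPM with CNO and 1177 ± 3.7 CPM with vehicle, which is a rise of 0.16 ± 0.021 (edgeR adjusted p = 0.00126, all 3 CNO libraries above all 3 vehicle libraries). In the deposited TPM values the levels were 969 ± 21.8 with CNO and 853 ± 13.6 with vehicle. The row does not separate the endogenous gene from an introduced receptor sequence. With CNO replicate 1 as the lone treated library, assumed to vary like the vehicle libraries, the change was 0.14 and the call was lost (edgeR adjusted p = 0.0701, the highest of its 23 alternatives, the lowest being 3.01e-10). It was also lost with the mean of the fibroblast marker list as a covariate, where the change was also 0.14 (edgeR adjusted p = 0.0504).

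Among the 30 rapid immediate early genes, those transcribed within minutes of stimulation without new protein synthesis, 23 rose and 28 passed when adjusted over the list alone. All 30 had a positive change, with a median of 1.63 (camera adjusted p = 1.82e-49, and adjusted p = 0.0028 with an estimated correlation). ARC, which encodes a cytoskeleton-associated protein of dendrites, went from 5.78 ± 0.275 CPM to 34.2 ± 0.695 CPM and NPAS4, a transcription factor of depolarised neurons, from 5.99 ± 0.0734 CPM to 35.4 ± 1.8 CPM (edgeR adjusted p = 4.55e-10 and 6.99e-10). The orphan nuclear receptor NR4A3 rose by 2.87 ± 0.064, to 97.1 ± 6.04 CPM, and NR4A1 by 1.91 ± 0.062, to 74.1 ± 5.54 CPM (edgeR adjusted p = 4.55e-10 and 3.49e-09). FOS, at 33.6 ± 0.547 CPM the most abundant of FOS, FOSB, FOSL1 and FOSL2 in the vehicle libraries, rose by 1.2 ± 0.039 (edgeR adjusted p = 3.21e-09). ZFP36, which encodes an mRNA-destabilising protein, rose by 2.96 ± 0.12 and CCN1, a matricellular protein, by 2.51 ± 0.060 (edgeR adjusted p = 2.75e-08 and 4.55e-10). EGR4 rested on 1.22 ± 0.358 CPM with CNO and 0.0825 ± 0.103 CPM with vehicle. BDNF, the neurotrophin commonly used as an activity readout, had 4.75 ± 0.61 CPM with CNO and 3.74 ± 0.0623 CPM with vehicle, and its change of 0.34 ± 0.13 did not pass (edgeR adjusted p = 0.243).

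**Figure D1:**
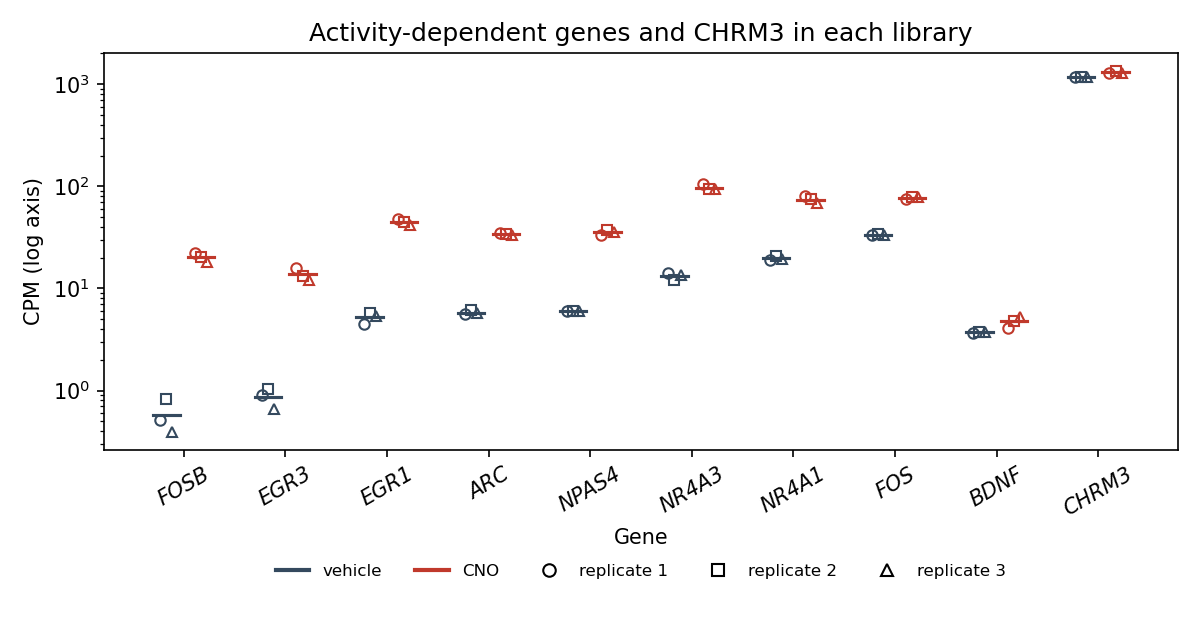
CPM on a log axis for 8 activity-dependent genes, BDNF and CHRM3, with 1 marker per library (circle, square and triangle for replicates 1, 2 and 3) and a bar at the mean of the 3 libraries of each group. The CNO libraries lie above the vehicle libraries for every gene drawn, by a log2 change of 5.17 for FOSB and of 0.34 for BDNF, whose change did not pass the test.

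Targets of serum response factor and the actin cytoskeleton rose in 13 of 16 members, 14 when adjusted over the list alone, with a median change of 0.72 (camera adjusted p = 8.44e-20, and adjusted p = 0.0234 with an estimated correlation). CCN2, a matricellular protein, rose from 29.6 ± 1.54 CPM to 134 ± 11.2 CPM. SRF itself rose by 0.77 ± 0.034 and VCL, which encodes the focal adhesion protein vinculin, by 0.66 ± 0.030 (edgeR adjusted p = 1.14e-09 for CCN2, 6.17e-08 for SRF and 7.15e-08 for VCL). TAGLN, a smooth muscle and fibroblast actin-binding protein, rose by 0.65 ± 0.052 (edgeR adjusted p = 1.45e-05). Outside the list, THBS1, the gene of the secreted matrix protein thrombospondin-1, was among the 10 largest rises, from 29.3 ± 1.78 CPM to 179 ± 18.6 CPM (edgeR adjusted p = 1.07e-09). Fibroblast markers differed between the CNO libraries at the same time: COL3A1 stood at 141 CPM in CNO replicate 1, 319 in replicate 2 and 348 in replicate 3, against 143 ± 24.1 CPM with vehicle. With CNO replicate 1 as the lone treated library, which is assumed to vary like the vehicle libraries, the list's median was 0.61 and 6 of its members were called.

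**Figure D2:**
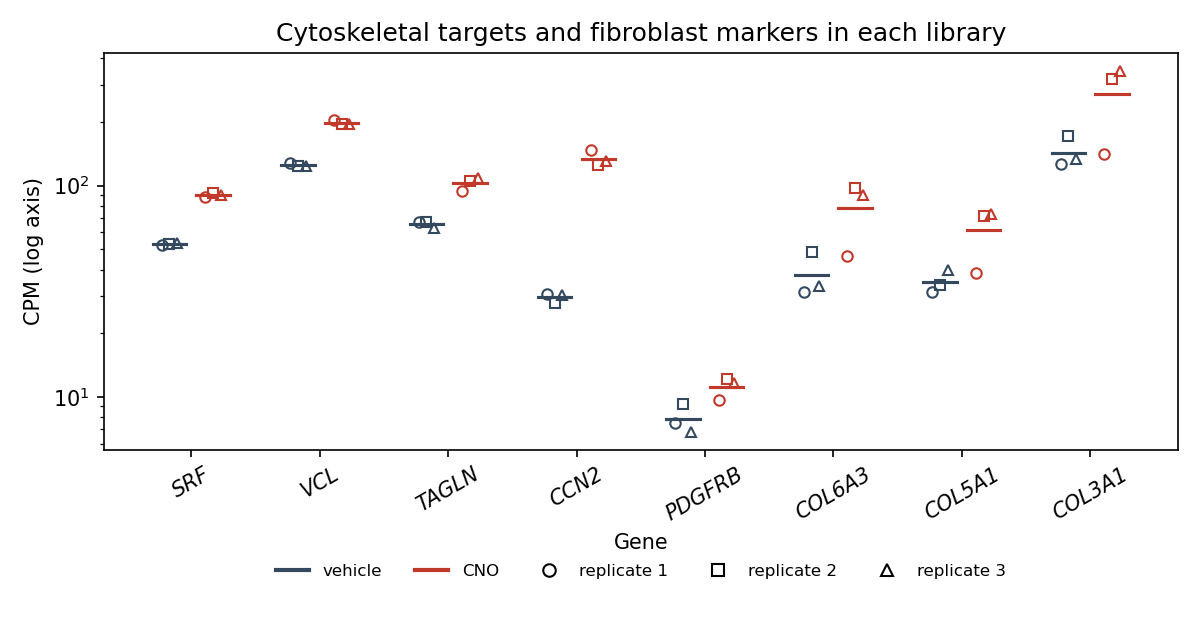
CPM on a log axis for 4 cytoskeletal target genes and 4 fibroblast markers, with 1 marker per library (circle, square and triangle for replicates 1, 2 and 3) and a bar at the mean of the 3 libraries of each group. For SRF, VCL, TAGLN and CCN2 all 3 CNO libraries lie above all 3 vehicle libraries, whereas CNO replicate 1 lies within the range of the vehicle libraries for COL3A1 (141 CPM), COL5A1 (38.5 CPM) and COL6A3 (46.6 CPM). For PDGFRB, CNO replicate 1 (9.69 CPM) lies just above the highest vehicle library (9.28 CPM in replicate 2).

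Feedback regulators of MAP kinase signalling rose in 9 of 20 members, or 13 when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 3.07e-11, and adjusted p = 0.0234 with an estimated correlation). They included the ERBB inhibitor ERRFI1 (0.51 ± 0.030), SPRY2 (0.55 ± 0.038) and SPRY4 (0.50 ± 0.049) of the Sprouty family and the phosphatase gene DUSP5 (0.75 ± 0.065), with edgeR adjusted p-values of 7.25e-07, 3.56e-06, 7.77e-05 and 2.92e-05. Of 21 CREB and cAMP targets 8 rose, 13 when adjusted over the list alone with 1 more passing downwards, with a median of 0.29 (camera adjusted p = 7.49e-11, and adjusted p = 0.0234 with an estimated correlation). The list shares 7 genes with the immediate early list. The 4 that rose outside it were the clock gene PER1 (0.79 ± 0.043), the small GTPase gene GEM (1.15 ± 0.14), the phosphodiesterase gene PDE4D (0.29 ± 0.039) and RGS2 (0.27 ± 0.045), which encodes a regulator of Gq signalling (edgeR adjusted p = 4.25e-07, 7.79e-04, 0.00126 and 0.00618). Of 24 genes of Gq and calcium signalling 4 rose, 5 when adjusted over the list alone. These were NFATC2, a calcineurin-dependent transcription factor, from 0.689 ± 0.159 CPM to 5.16 ± 0.503 CPM, the calcineurin inhibitor RCAN1 (0.78 ± 0.037), RGS16 (0.38 ± 0.061) and RGS2 (edgeR adjusted p = 3.04e-06, 1.18e-07, 0.0048 and 0.00618). This list had a median of only 0.024 (camera adjusted p = 0.0319, but adjusted p = 0.298 with an estimated correlation). Its call was lost without CNO replicate 1 (camera adjusted p = 0.0982), without CNO replicate 2 (0.0997) and without vehicle replicate 1 (0.0746), in a range of 0.00598 to 0.298 over its alternatives. The GC correction also removed this call (camera adjusted p = 0.245).

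LIF, a cytokine of the interleukin-6 family, went from 3.11 ± 0.383 CPM to 13.6 ± 0.905 CPM (edgeR adjusted p = 1.77e-07). The heparin-binding growth factor HBEGF rose by 0.37 ± 0.058 and the angiogenic factor VEGFA by 0.37 ± 0.055 (edgeR adjusted p = 0.00396 and 0.00272). These were the 3 members called among 21 neurotrophins, growth factors and their receptors, against 7 when adjusted over the list alone (median 0.16, camera adjusted p = 2.35e-04, but adjusted p = 0.0694 with an estimated correlation). Without vehicle replicate 1 edgeR called 5 of them. INHBA, the activin A subunit, had a change of 0.47 ± 0.13 that did not pass (edgeR adjusted p = 0.0813), though it did pass without vehicle replicate 1 (0.61, adjusted p = 0.0245, in a range of 0.00164 to 0.279 over its alternatives). Among 11 NF-kappaB and inflammatory genes all had a positive change, 3 rose and 7 passed when adjusted over the list alone (median 0.34, camera adjusted p = 3.02e-09, and adjusted p = 0.0234 with an estimated correlation). The 3 were LIF, the chemokine CCL2, from 7.08 ± 0.388 CPM to 16.5 ± 1.33 CPM, and the NF-kappaB subunit RELB, which rose by 0.68 ± 0.12 (edgeR adjusted p = 3.04e-06 and 0.00658).

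Genes of the cholesterol pathway rose in 11 of 17 members, 13 when adjusted over the list alone with 1 more passing downwards, with a median of 0.22 (camera adjusted p = 3.20e-12, but adjusted p = 0.124 with an estimated correlation). Among them INSIG1, a regulator of sterol synthesis, rose by 0.68 ± 0.041 and the isomerase gene IDI1 by 0.39 ± 0.030 (edgeR adjusted p = 9.12e-07 and 9.51e-06). Of 16 genes of the unfolded protein response 5 rose, 12 when adjusted over the list alone (median 0.14, camera adjusted p = 1.18e-09, and adjusted p = 0.0333 with an estimated correlation). Besides ATF3, which is also an immediate early gene, these were the endoplasmic reticulum chaperone HSPA5 (0.23 ± 0.023), HERPUD1 (0.31 ± 0.031), PPP1R15A (0.28 ± 0.031) and DDIT3 (0.36 ± 0.059), with edgeR adjusted p-values of 1.06e-04, 1.25e-04, 2.41e-04 and 0.00557.

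Other stress and metabolic lists held few called genes. In the p53 and DNA damage list 2 of 15 rose, 3 when adjusted over the list alone. These were GADD45A by 0.80 ± 0.054 and the cell cycle inhibitor CDKN1A by 0.18 ± 0.031 (edgeR adjusted p = 3.04e-06 and 0.00806). CDKN1A was not called without vehicle replicate 3 (0.16, edgeR adjusted p = 0.0579, in a range of 5.93e-07 to 0.0756 over its alternatives). The p53 list's camera adjusted p was 6.24e-04, but adjusted p = 0.224 with an estimated correlation. In the hypoxia and glycolysis list 2 of 15 rose, 4 when adjusted over the list alone. They were the glycolytic regulator PFKFB3 by 0.57 ± 0.033 (edgeR adjusted p = 6.93e-07) and VEGFA. Camera gave this list an adjusted p of 0.00426 (but adjusted p = 0.124 with an estimated correlation). In the circadian clock list 2 of 15 rose, 5 when adjusted over the list alone: PER1 and BHLHE41, the latter by 0.47 ± 0.081 (edgeR adjusted p = 0.00727). The clock list's camera adjusted p was 0.0138, but adjusted p = 0.142 with an estimated correlation. PER2 had a change of 0.34 ± 0.082 that did not pass (edgeR adjusted p = 0.0526). Among fits without 1 library it passed when vehicle replicate 2 was left out (0.45, edgeR adjusted p = 0.00536, in a range of 8.74e-05 to 0.361 over its alternatives). In the heat shock list the co-chaperone BAG3 was the single member of 14 called (0.30 ± 0.049, edgeR adjusted p = 0.00497), against 3 when adjusted over the list alone and 2 without CNO replicate 3. The heat shock list passed camera at an adjusted p of 0.0386, but had an adjusted p = 0.379 with an estimated correlation. Its call was also lost without CNO replicate 1 (0.0531), without CNO replicate 3 (0.184), without vehicle replicate 1 (0.152) or without vehicle replicate 3 (0.0754), in a range of 0.0196 to 0.379 over its alternatives. The GC correction removed it too (camera adjusted p = 0.207).

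Late-response activity genes, whose transcription follows that of the immediate early factors, held few called genes at 2 h. Of 24 members 2 rose, 6 passed upwards and 1 downwards when adjusted over the list alone, and the median was 0.070. GPR3, a constitutively active receptor gene, went from 2.94 ± 0.0599 CPM to 7.02 ± 0.263 CPM, and the secretogranin gene SCG2 rose by 0.18 ± 0.029 (edgeR adjusted p = 2.74e-05 and 0.00412). HOMER1 had a change of 0.16 ± 0.041 and the prohormone convertase gene PCSK1 of 0.21 ± 0.051, neither of which passed (edgeR adjusted p = 0.0739 and 0.0587). PCSK1 did pass without vehicle replicate 2 (0.27, edgeR adjusted p = 0.00861, in a range of 3.76e-04 to 0.254 over its alternatives). The list's camera adjusted p was 0.0138, but adjusted p = 0.127 with an estimated correlation and 0.063 without vehicle replicate 1, in a range of 0.00231 to 0.265 over its alternatives.

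Camera called 3 lists lower. The 13 mRNAs encoded by the mitochondrial genome had a median change of -0.16, and 9 fell, 12 when adjusted over the list alone (camera adjusted p = 1.80e-06, but adjusted p = 0.379 with an estimated correlation). Fry did not call this list (fry adjusted p = 0.0859). MT-CO3 was at 2159.8 ± 79.5 CPM with CNO and 2563 ± 158 CPM with vehicle (edgeR adjusted p = 0.00433). MT-CYB had a change of -0.20 ± 0.038 (edgeR adjusted p = 0.013). That p was 0.0539 without CNO replicate 1, 0.0807 without CNO replicate 2, 0.0845 without vehicle replicate 2 and 0.0559 without vehicle replicate 3. Together these 13 mRNAs took 3.15, 3.03 and 3.16% of counts in CNO replicates 1, 2 and 3 and 3.3, 3.54 and 3.72% in vehicle replicates 1, 2 and 3. Their number of called members moved with single libraries, to 2 without CNO replicate 1, 1 without CNO replicate 2, 3 without CNO replicate 3, 2 without vehicle replicate 2 and 2 without vehicle replicate 3. All 18 tested HOX genes, which mark hindbrain and spinal cord position, had a negative change, with a median of -0.090 (camera adjusted p = 9.66e-07, but adjusted p = 0.127 with an estimated correlation). Of them HOXB3 (-0.14 ± 0.027), HOXB6 (-0.13 ± 0.029) and HOXD3 (-0.18 ± 0.040) fell, and 10 did so when adjusted over the list alone (edgeR adjusted p = 0.0128, 0.0336 and 0.0366). The number called was 1 without any one of the 3 CNO replicates, 2 without vehicle replicate 2 and 0 by edgeR without vehicle replicate 3. With all libraries DESeq2 called 6 and limma-voom 3, and 10 had an unadjusted p under 0.05. On log2(TPM + 1) HOXB3, HOXB6 and HOXD3 had changes of -0.127, -0.08 and -0.121. None of them was called there (limma adjusted p = 0.293, 0.466 and 0.33). Left-out libraries took the edgeR adjusted p of HOXB3 up to 0.0789, of HOXB6 up to 0.165 and of HOXD3 up to 0.159. Presynaptic genes had a median of -0.040 over 24 members, of which edgeR called 0, DESeq2 1 higher and 1 lower and limma-voom 0, while 7 had an unadjusted p under 0.05. Of the 24, 1 passed upwards and 3 downwards when adjusted over the list alone, and edgeR called 1 higher without CNO replicate 3 or vehicle replicate 1. Fry did not call these genes as a list (fry adjusted p = 0.214). Their camera adjusted p of 0.0169 was lost with an estimated correlation (adjusted p = 0.589) and after the GC correction (adjusted p = 0.104). It was also lost without CNO replicate 1 (0.0521), without CNO replicate 3 (0.126), without vehicle replicate 1 (0.063) and without vehicle replicate 2 (0.223), in a range of 0.00305 to 0.589 over its alternatives.

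**Figure D3:**
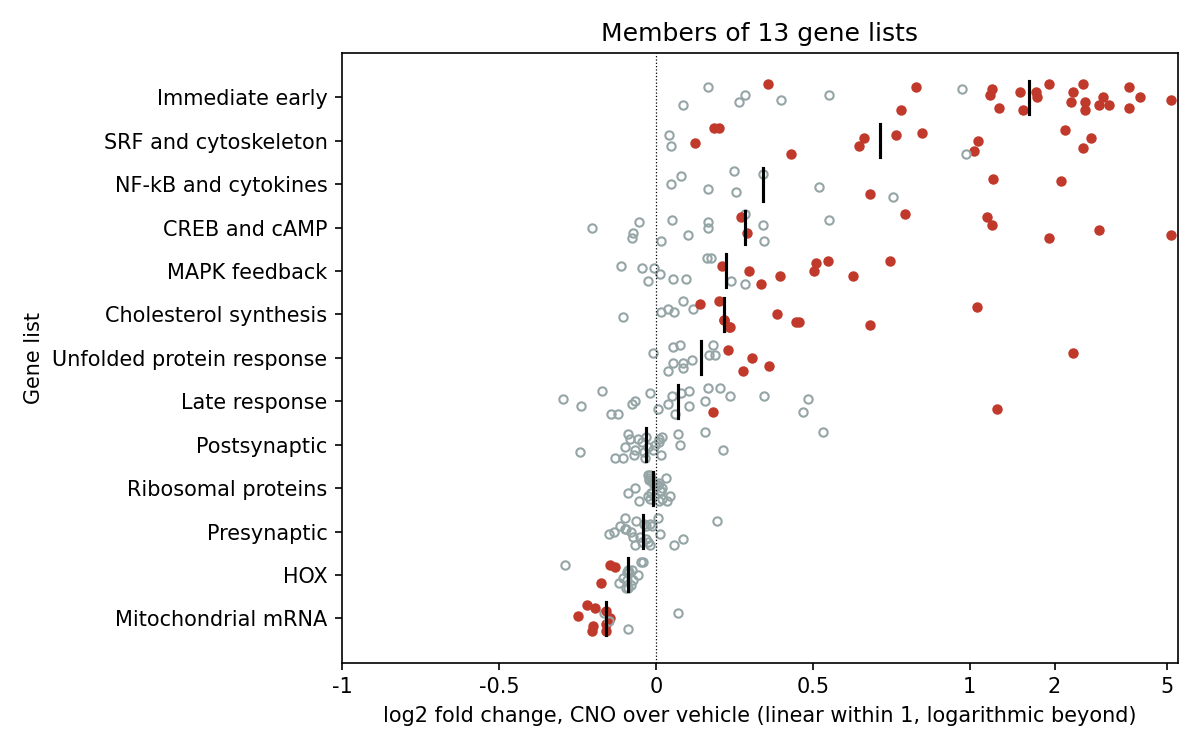
Log2 fold change of CNO over vehicle (linear within 1 of 0, logarithmic beyond) for the tested members of 13 gene lists, with filled red points for called genes (edgeR), open grey points for the others and a vertical bar at each list's median. The immediate early list has its median at 1.63 and the mitochondrial list at -0.16, while the postsynaptic list, with no called member, has its median at -0.031.

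The largest falls that the naming rule selects, pseudogenes aside, lay between -0.62 and -0.34. TXNIP, a thioredoxin-binding regulator of glucose uptake, had 43.8 ± 1.7 CPM with CNO and 55.5 ± 2.95 CPM with vehicle, a change of -0.34 ± 0.048 (edgeR adjusted p = 0.00202). PIK3IP1, an inhibitor of PI3 kinase, had a change of -0.36 ± 0.064 and CEACAM19 of -0.45 ± 0.078 (edgeR adjusted p = 0.00972 and 0.00806). On log2(TPM + 1) none of TXNIP, PIK3IP1 and CEACAM19 was called (limma adjusted p = 0.0552, 0.158 and 0.0523). CEACAM19 was not called without vehicle replicate 3 (edgeR adjusted p = 0.0534, in a range of 8.63e-05 to 0.158 over its alternatives). The transcription factor gene SP9 (-0.36 ± 0.070), FBXL6 (-0.35 ± 0.069), IDUA (-0.42 ± 0.10) and the readthrough row TEN1-CDK3 (-0.62 ± 0.14), which shares exons with TEN1 and CDK3, were also among the 10 largest falls (edgeR adjusted p = 0.016, 0.016, 0.0476 and 0.0449). Each of these last 4 lost its call without at least 3 of the 6 libraries taken singly. SP9 did so without CNO replicate 1, CNO replicate 2 or vehicle replicate 2 (edgeR adjusted p up to 0.0935). FBXL6 did so without CNO replicate 1, CNO replicate 2, vehicle replicate 2 or vehicle replicate 3 (up to 0.096), and IDUA without those same 4 libraries (up to 0.214). TEN1-CDK3 lost it without CNO replicate 2, CNO replicate 3, vehicle replicate 1 or vehicle replicate 2 (up to 0.191).

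A further 4 rows among the falls have near-identical copies, so that their reads could be shared out differently, and are uncertain. SLC2A3P1, a pseudogene of the glucose transporter gene SLC2A3, had 0 counts over the 3 CNO libraries and 241 over the vehicle libraries, which is at least 81.4-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 7.93e-06). Summed with SLC2A3 and SLC2A14 the level was 42.1 ± 1.31 CPM with CNO and 34.8 ± 2.73 CPM with vehicle, so that the sum was higher, not lower, with CNO in all 3 libraries. RAB43P1 had 0 against 75 counts, at least 25.3-fold lower (edgeR adjusted p = 8.74e-04), and its sum with RAB43 was 15.7 ± 2.16 CPM with CNO and 13.5 ± 2.83 CPM with vehicle. PKD1P1 had 11.2 ± 1.6 CPM with CNO and 18 ± 1.06 CPM with vehicle (edgeR adjusted p = 0.00156), against 512 ± 20.8 CPM and 568 ± 25.6 CPM for the 7 rows of PKD1 and its numbered pseudogenes together. FAM156A had 26.5 ± 2.63 CPM and 37.1 ± 2.52 CPM (edgeR adjusted p = 0.00265), against 63.8 ± 2.25 CPM and 71.5 ± 4.4 CPM for its sum with the copy FAM156B.

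Camera called 3 lists of cell types other than neurons higher. In the astrocyte list the glutamine synthetase gene GLUL rose by 0.32 ± 0.030 and the connexin 43 gene GJA1 by 0.39 ± 0.051 (edgeR adjusted p = 5.54e-05 and 0.0011). These were 2 of 14 members, or 6 when adjusted over the list alone, with a median of 0.10 (camera adjusted p = 9.97e-04, but adjusted p = 0.198 with an estimated correlation). In the mesenchymal and fibroblast list COL6A3 (1.05 ± 0.23) and PDGFRB (0.51 ± 0.12) rose (edgeR adjusted p = 0.034 and 0.0444). These were 2 of 12 members, or 11 when adjusted over the list alone, with a median of 0.78 (camera adjusted p = 1.80e-04, but adjusted p = 0.468 with an estimated correlation). Fry did not call the fibroblast list (fry adjusted p = 0.206). PDGFRB stood at 9.69 CPM in CNO replicate 1, above the 7.49, 9.28 and 6.85 CPM of vehicle replicates 1, 2 and 3. The rise of the list's mean lay in CNO replicates 2 and 3. The mean of the list was 4.73 log2 CPM in CNO replicate 1, 5.58 in replicate 2 and 5.61 in replicate 3, against 4.5, 4.86 and 4.68 in vehicle replicates 1, 2 and 3. The number called was 10 without CNO replicate 1, 1 without vehicle replicate 2 and 0 without any one of CNO replicates 2 and 3 and vehicle replicates 1 and 3, with list medians of 0.54 to 0.78 in those last 4 fits. On all libraries limma-voom also called 0, while DESeq2 called 2 and 11 had an unadjusted p under 0.05. COL6A3 lost its call without any library but CNO replicate 1 (edgeR adjusted p up to 0.178) and PDGFRB without CNO replicate 2 or 3 or vehicle replicate 1 or 3 (up to 0.2). In the neural crest and Schwann cell list the transcription factor gene ETS1 rose by 1.37 ± 0.17 (edgeR adjusted p = 6.06e-04). Its call was lost on log2(TPM + 1) (0.73, limma adjusted p = 0.257) and with effective length offsets (1.1, edgeR adjusted p = 0.185). ETS1 was 1 of 9 members called, or 2 without CNO replicate 2 and 2 when adjusted over the list alone. The list's camera adjusted p was 0.00847, but 0.127 with an estimated correlation. It was 0.0756 with the mean of the fibroblast list as a covariate.

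The remaining 21 of the 41 lists were not called by camera (adjusted p from 0.192 to 0.915). In 4 of them single genes rose. They were NOTCH3 (0.27 ± 0.033) and its ligand JAG1 (0.25 ± 0.054) among 13 Notch pathway genes. Among 9 Wnt pathway genes they were the ligand gene WNT7A (0.29 ± 0.052) and NKD1 (0.19 ± 0.039). Also higher were TFRC (0.23 ± 0.039) and B2M (0.13 ± 0.031) among 14 housekeeping genes, and TEK (1.03 ± 0.23) among 3 endothelial genes (edgeR adjusted p from 6.11e-04 to 0.039). Adjusted over the list alone, 2 Notch, 2 Wnt, 2 housekeeping and 1 endothelial genes passed upwards and 1 Notch gene downwards. The endothelial count was 0 without any one of the 6 libraries. The Wnt count was 0 without CNO replicate 1 or vehicle replicate 2 and 1 without CNO replicate 3, vehicle replicate 1 or vehicle replicate 3. The Notch count was 1 without CNO replicate 1, CNO replicate 3, vehicle replicate 2 or vehicle replicate 3, with 1 Notch gene lower without CNO replicate 3. The housekeeping count was 1 without any library but CNO replicate 2. With all libraries DESeq2 and limma-voom each called 2 Notch, 2 Wnt, 2 housekeeping and 1 endothelial genes, and 5, 2, 2 and 1 had an unadjusted p under 0.05. The other 17 held 209 tested genes, of which edgeR called 0, limma-voom 0 and DESeq2 3 (CACNA1H, VIM and INA). Of the 209, 34 had an unadjusted edgeR p under 0.05, where chance gives 10.45. Over all tested rows 2841 of 18646 had such a p. EdgeR called 1 postsynaptic and 1 glutamatergic gene higher without CNO replicate 3 or vehicle replicate 1. It called 1 ribosomal protein gene lower without CNO replicate 3, 1 progenitor marker higher without vehicle replicate 1, 1 general neuron marker lower without vehicle replicate 3 and 1 microglia marker higher without CNO replicate 1. The 17 were the lists of postsynaptic genes, voltage-gated channels, interferon response, cell cycle, ribosomal proteins and replication histones, and of neural stem and progenitor cells, neurons in general, glutamatergic, GABAergic, cholinergic and monoaminergic neurons, forebrain position, oligodendrocyte lineage, microglia, choroid plexus and pluripotent cells. Their median changes ran from -0.058 for histones to 0.054 for progenitor markers, leaving out the microglia list with 2 tested genes. Adjusted over the list alone, 4 progenitor markers passed upwards and 3 downwards, 2 postsynaptic genes upwards and 1 downwards, and 1 gene each upwards in the glutamatergic and monoaminergic lists and downwards in the general neuron list. Of 17 general neuron markers 5 had a positive and 12 a negative change (median -0.032). INA, which encodes a neurofilament protein, had 928 ± 16.3 CPM with CNO and 994 ± 27.1 CPM with vehicle (-0.10 ± 0.025, edgeR adjusted p = 0.0648), and MAP2 had 1455 ± 60.4 CPM and 1396 ± 35.4 CPM (0.060 ± 0.030, edgeR adjusted p = 0.379).

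The test rested on 3 libraries per group, and no sample of cells without the receptor was treated with CNO, so an effect of the drug apart from hM3Dq is not separated here. In 5 simulated draws with the real means, 50.4% of 1.2-fold and 82% of 2-fold changes were recovered under trended dispersions and 46.4% and 76% under dispersions estimated per row, so small changes that did not pass are not shown to be absent.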

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

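The alternatives with symbol rows only, CNO replicate 1 alone, the fibroblast covariate, GC, length, effective lengths and the newer edgeR fit were chosen after the results were seen. Against 431 genes higher and 67 lower, edgeR gave 934 and 553 with no low-count filter, where its prior degrees of freedom became effectively infinite (mean 7.48 in the fit behind the reported counts), and the newer edgeR fit with no filter gave 462 and 94. The lower count became 190 with the 10 CPM filter, 157 with the replicate block (559 higher), 166 with symbol rows only, 138 with the fibroblast covariate and 116 with the length correction. Counts were 181 and 13 on log2(TPM + 1), 190 and 14 on log2(TPM + 0.1), 195 and 18 with effective length offsets, and 228 and 40 with CNO replicate 1 alone, a lone sample assumed to vary like the vehicle group. Leaving out 1 library gave 284 to 402 higher (284 without vehicle replicate 3) and 27 to 133 lower (27 without CNO replicate 2, 133 without vehicle replicate 1). Beyond the filters and smaller sets named, the cause was not tested. RLE, library size, DESeq2, limma-voom and GC gave 380 to 447 higher and 58 to 97 lower. The GC correction nevertheless removed the calls of the presynaptic, Gq and calcium, and heat shock lists. Among named genes it removed those of IDUA, TEN1-CDK3 and HOXB6 (edgeR adjusted p = 0.0843, 0.062 and 0.0738). Of the 17 lists higher and 3 lower, 6 and 0 were called with an estimated correlation, against 16 and 1 by fry, 13 and 3 with ranks, and 14 to 17 and 2 to 3 without 1 library. COL3A1 turned to -0.011 with CNO replicate 1 alone and to -0.0634 with the fibroblast covariate, under which the fibroblast list's adjusted p was 0.955, since the covariate is that list's own mean. Over all tested rows, CNO and vehicle libraries of the same replicate number correlated by -0.0044, 0.044 and 0.060 after removal of group means. CNO replicates 2 and 3 correlated best with the vehicle replicates of their own number. CNO replicate 1 did so with vehicle replicate 2. These correlations weigh low-count rows like all others, and the replicate block gave more calls (559 higher and 157 lower). Whether the replicate numbers pair the samples therefore stays open. Over 94 named genes, 1885 of 2139 comparisons with an alternative kept direction and side of the threshold, 156 lost the call, 96 gained it and 2 reversed. For the 20 called lists these were 291 of 340, 48, 0 and 1. Depths of 20010285 to 30157141 counts limit what rows near the floor of 0.0992 to 0.15 CPM can show.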

Other observations

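The tests of other splits, of the fibroblast covariate, of GC content and length, of transcript lengths, of nuclear respiratory chain genes and of the interleukin-6 family were chosen after the results were seen. The EGR co-repressors rose alongside EGR1, EGR2 and EGR3: NAB2 went from 33.7 ± 0.906 CPM to 66.3 ± 1.2 CPM, a change of 0.97 ± 0.039, and NAB1 rose by 0.24 ± 0.040 (edgeR adjusted p = 2.75e-08 and 0.0058). Besides LIF, the cytokine CLCF1 rose by 1.59 ± 0.20, from 1.14 ± 0.17 CPM to 3.39 ± 0.373 CPM, and the receptor gene IL6R by 1.96 ± 0.21, from 1.09 ± 0.327 CPM to 4.31 ± 0.292 CPM (edgeR adjusted p = 6.93e-04 and 1.87e-04). The shared receptor subunit IL6ST (0.16 ± 0.032), the transcription factor STAT3 (0.16 ± 0.027) and the feedback inhibitor SOCS3 (0.33 ± 0.076) rose by less (edgeR adjusted p = 0.0164, 0.00689 and 0.0401).

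The listed targets of serum response factor and the actin cytoskeleton rose while fibroblast markers were higher in CNO replicates 2 and 3. More fibroblast-like cells in those libraries could therefore account for the rise. With the fibroblast list mean as a covariate, the median change of the 13 called targets was 0.73 against 0.77 without it. The SE of this shift was 0.033 over genes, and 11 targets were still called. The fibroblast list's own median went from 0.78 to 0.0025. The small shift of the targets argues against fibroblast number as the whole cause of the rise. With 6 libraries and 1 covariate the fit is small, and a stronger response within fibroblast-like cells stays open, since cell types were not measured separately.

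The fall of all 18 HOX genes, with a median of -0.090, could come from a technical trend across libraries. After a correction for GC content the median was -0.099 (SE 0.016), and after one for transcript length -0.096 (SE 0.016). These SEs hold the spread over the 18 genes, not between libraries. In the same corrections the median of all tested rows was -0.018 and -0.015. These values argue against either trend as the whole cause. With the deposited effective lengths as offsets, HOXB3, HOXB6 and HOXD3 kept changes of -0.162, -0.115 and -0.156. Their calls were lost in that fit (edgeR adjusted p = 0.107, 0.26 and 0.229). A small difference in the regional make-up of the cultures, or a response to CNO, stays open as an untested hypothesis, and the list's call was lost with an estimated correlation (camera adjusted p = 0.127).

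The 13 mitochondrial mRNAs had a median of -0.16, and a common fall of respiratory chain transcripts could include them. The median of 30 nuclear-encoded respiratory chain genes was -0.028 (SE over genes 0.0083). Their smallest edgeR adjusted p was 0.23, for UQCRFS1. Camera placed these 30 genes lower at an unadjusted p of 0.0481. Over the 4 added lists the camera adjusted p was 0.0642, and 0.607 with an estimated correlation. A smaller fall of the nuclear genes stays open. The median of -0.028 argues against a fall shared by both genomes at the size seen in the mitochondrial list. That list's own call was lost with an estimated correlation (camera adjusted p = 0.379) and by fry (fry adjusted p = 0.0859). Differences in mitochondrial RNA content or handling between the groups were not tested, and vehicle replicate 1 lay closest to the CNO libraries (3.3% of counts).

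With 10 splits of the 6 samples into 3 and 3, a share under 0.05 cannot be reached: 1 of the 10, the real one, gave 431 genes higher, 67 lower and 20 called lists. The highest of the other splits was 3 genes in 1 direction, counted in its larger direction since a split and its mirror are the same, and 9 called lists. Each other split mixes CNO and vehicle libraries on both sides, so the CNO difference adds to its spread within groups. Few gene calls are then built in, and the contrast with the real split decides nothing about chance. The interleukin-6 hypothesis was left undecided: the other 13 members had a median of 0.11 (SE over genes 0.093) and 3 were called. Over the 4 added lists they passed with the preset correlation (camera adjusted p = 0.0159) but not with an estimated correlation (adjusted p = 0.0986). The adjustment over lists was added to the latter test after its unadjusted p of 0.0493 had been seen. For a shift to the shorter transcripts of HOMER1 and CREM, the deposited mean length changed by -0.022 (95% interval -0.15 to 0.10) and 0.0090 (-0.17 to 0.19) on the log2 scale, which leaves it undecided. Over 12148 rows tested for length, limma called 0, while 659 had an unadjusted p under 0.05 against 607 by chance.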
